A study of Mus musculus with 16 samples.

How the data were processed

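Heart samples in 4 groups of 4 were profiled by bulk RNA sequencing. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit; strandedness is not given in the sources used here, so reads of a gene and an overlapping antisense partner cannot be told apart. The deposited count table holds whole-number counts for 24371 genes (17627 protein coding). Per the submitters' processing notes, fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2 were used with the GRCm39 build; their roles and settings are not stated, so losses to multiply mapped reads between near-identical genes are unknown. A second deposited table holds FPKM made by the authors from the same counts: each FPKM value equalled the count scaled by the library total and a single gene length, to a relative spread of 7.5e-16. All 16 labels share a batch value, and the labels do not say that the samples came from separate animals, so p-values measure the spread between these samples.

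Counts were analysed as deposited. Library totals were 27835235 to 34700996 counts, and with 3 counts as the floor the smallest level told from 0 was 0.0865 to 0.108 CPM, which covers counting error only. Replicate libraries of a group correlated at r = 0.978 to 0.988 and differed by far more than sampling noise (chi-square per degree of freedom of 11.4 to 62.1), so none was counted as a repeat. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 14607 genes holding at least 99.95% of the counts. Normalisation used TMM factors, which ranged from 0.946 to 1.09. The main test was edgeR 4.0.16 (robust quasi-likelihood F-test, R 4.3.3), with a mean for each of the 4 groups in 1 fit, 12 residual degrees of freedom, and Benjamini-Hochberg adjustment to 0.05; the common biological coefficient of variation was 0.159. The comparisons were succinate within each genotype, genotype with and without succinate, and the interaction. Adjusted p-values of single genes in the text come from these edgeR tests unless another tool is named. Those of gene lists come from the camera tests described below.

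A set of 41 gene lists covering metabolism, stress, inflammation, the clock and cell types of the heart was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists in each comparison, and again with a correlation estimated from the data. Counts of members that passed are given over all tested genes and adjusted over the list alone. Named genes were Sucnr1, the 10 highest and 10 lowest fold changes that passed with a mean log2 CPM of at least 1 and a plain symbol, up to 4 members that passed in each list, up to 2 members of smallest p for central lists with none, and the 10 genes of smallest p where fewer than 5 passed; genes outside the rule are named as chosen afterwards. Some genes that the rule takes are not reported here. Sucnr1 did not enter the tested set and was compared by a two-sided exact permutation test of CPM, 8 hearts against 8.

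On simulated counts with known changes, edgeR recovered 53.7%, 71.2% and 86.4% of genes changed 1.5-fold, 2-fold and 3-fold for succinate in floxed hearts (14423 genes), and 23.9%, 59.1% and 75.8% for the interaction. False calls were 11 of 151 and 9 of 114. The simulated genes were drawn independently, without the correlation between genes of real libraries, so these rates may not carry over. Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE size factors, removal of mitochondrially encoded genes, no filter and a stricter filter on low counts, only the groups compared, a replicate block, atrial and white adipocyte marker scores as covariates, limma on log2 of the deposited FPKM with a pseudocount of 1 or 0.1 or a minimum mean of 1, and leaving out each library. Chromosomes were taken from a RefSeq table of the GRCm38.p6 assembly, matched by Entrez identifier (23549 of 24371 genes); because the builds differ, no coordinates are given. Gene Ontology terms came from the deposited annotation, and 3653 terms of 10 to 500 genes were tested against the 13869 tested genes with a term.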

Results

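Bulk RNA was sequenced from 16 mouse heart samples carrying a model of heart failure with preserved ejection fraction (HFpEF), induced over 12 weeks by a high-fat diet together with L-NAME, an inhibitor of nitric oxide synthase. The hearts formed 4 groups of 4. Mice with both alleles of Gpr91 floxed (floxed hearts) were compared with mice that also carried the cardiomyocyte-expressed Myh6-Cre transgene (Cre hearts, labelled as cardiomyocyte knockouts of this receptor gene). Each genotype was studied with and without succinate, the tricarboxylic acid (TCA) cycle intermediate that activates this receptor. The series title names cardiomyocyte metabolism and NAD production as its subject. Total counts ranged from 27835235 to 34700996 per library, and 18038 to 19130 genes had at least 1 count. Mitochondrially encoded genes took 23.5% to 27.7% of the counts. After filtering, 14607 genes were tested.

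The floxed gene, Sucnr1 (the current symbol of Gpr91), had few counts in every library, from 0 to 21. In replicates 1 to 4 its counts were 0, 4, 1 and 1 in floxed hearts without succinate and 5, 2, 7 and 0 with it. In Cre hearts they were 2, 6, 21 and 3 without succinate and 13, 3, 13 and 2 with it. A count of 3 corresponded to 0.0865 to 0.108 CPM, the count scaled by the library total. The mean was 0.0798 ± 0.0805 CPM in floxed hearts and 0.248 ± 0.224 CPM in Cre hearts (SD, n = 8 each), from 20 and 63 counts in total. The difference of 0.168 CPM did not pass a two-sided exact permutation test (p = 0.0657). Leaving out replicate 3 of the floxed hearts given succinate, replicate 1 or 4 of the untreated Cre hearts, or replicate 2 or 4 of the Cre hearts given succinate brought the exact p to 0.0462, 0.0329, 0.0448, 0.0426 and 0.0326. Without replicate 3 of the untreated Cre hearts the difference was 0.109 CPM. Sucnr1 was thus not lower in the hearts labelled Myh6-Cre, at a depth that gives no check of a cardiomyocyte deletion, and genotype below refers to the labels.

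The first comparison asked what succinate changed in floxed hearts. Genes of cardiac stress fell and genes of fatty acid use rose. Myh7, the slow myosin heavy chain of the fetal and stressed ventricle, fell by 4.03 ± 0.44 on the log2 scale (SE, n = 4 per group), from 4369.9 ± 1946 to 268 ± 29.2 CPM (SD). Ehhadh, a peroxisomal enzyme of fatty acid oxidation, rose 5.99-fold from 8.30 ± 2.45 to 49.8 ± 11.6 CPM. Ucp3, a mitochondrial carrier induced by fatty acids, rose 7.42-fold, and Pdk4, the kinase that restrains pyruvate oxidation, rose by 2.58 ± 0.63 on the log2 scale, from 673 ± 596 to 4037 ± 911 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1917 of 14607 genes passed 0.05, 1093 higher and 824 lower, and 307 of them changed at least 2-fold.

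Of the 15 cardiac stress and fetal genes, 7 fell, 0 rose and 8 did not pass, with 11 falling when adjusted over the list alone. Besides Myh7, the natriuretic peptide gene Nppb changed by -2.32 ± 0.30, the stretch-responsive Ankrd1 by -1.65 ± 0.17 and Xirp2 by -1.05 ± 0.21 (log2, SE). Nppa, the atrial natriuretic peptide gene, changed by -1.92 ± 0.44. Myh6, the main adult myosin heavy chain, rose by 0.69 ± 0.13; it is a close relative of Myh7, and reads the counting could assign to either are uncertain. The list passed camera at its preset correlation (adjusted p = 1.0e-11) and not with an estimated correlation (adjusted p = 0.123). Fry, a planned further test of whether a list moved in 1 direction, gave an unadjusted p = 4.6e-05 for its fall. Fry does not set a list against the other genes, and its values for other lists are not reported here. The 7 atrial markers, a list that shares Nppa, had a median of -0.23 (adjusted p = 0.264). Gdf15, a stress-induced secreted factor, changed by -3.29 ± 0.43, and Tnfrsf12a, a receptor induced by injury, by -1.92 ± 0.28.

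Fatty acid oxidation genes moved one way: 13 of 25 rose, 0 fell and 12 did not pass, with 18 rising when adjusted over the list alone. The carnitine enzymes Cpt1a and Cpt2 rose by 0.78 ± 0.14 and 0.59 ± 0.11, and the transporter Slc27a1 by 1.01 ± 0.15. Among 13 tested targets of PPAR-alpha, the nuclear receptor that induces fatty acid use, 9 rose and 0 fell (10 rose when adjusted over the list alone), including the acyl-CoA thioesterase Acot1 (2.05 ± 0.54, with close paralogs), Plin5 (0.88 ± 0.16) and Slc25a34 (0.74 ± 0.14). The camera calls of these lists (adjusted p = 1.0e-11 and 6.0e-10) were lost at adjusted p = 0.343 with an estimated correlation, the same value for both. Cardiomyocyte sarcomere genes, measured beside them, had a median of 0.02 over 17 genes (adjusted p = 0.230). In branched-chain amino acid catabolism, 10 of 19 genes rose and 0 fell (13 rose when adjusted over the list alone), led by Ppm1k, the phosphatase that activates the pathway's dehydrogenase (0.90 ± 0.12), and Bcat2 (0.41 ± 0.08); its adjusted p = 3.4e-08 became adjusted p = 0.343 with an estimated correlation. In the TCA cycle 5 of 20 genes rose and 0 fell (10 rose when adjusted over the list alone), among them Idh3a (0.46 ± 0.09) and Cs (0.40 ± 0.10), with adjusted p = 1.2e-05 and adjusted p = 0.477 with an estimated correlation. Of 5 genes of ketone body use 1 rose and 1 fell (2 and 1 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.146). Oxct1, which starts ketone body use in mitochondria, rose by 0.67 ± 0.09. Of 22 genes of lipid synthesis and storage, 8 rose and 3 fell (9 and 6 when adjusted over the list alone), and the list did not pass (adjusted p = 0.0651); Gpam rose by 1.06 ± 0.17 and the lipase Pnpla2 by 0.70 ± 0.13.

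NAD genes did not move together. Of 15 tested genes of NAD synthesis and transport, 2 rose, 1 fell and 12 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.619). Naprt, which makes NAD from nicotinic acid, rose by 0.53 ± 0.12, and the mitochondrial NAD kinase gene Nadk2 rose by 0.62 ± 0.14. Nmrk2, the muscle nicotinamide riboside kinase, changed by -3.27 ± 0.69. Of 14 NAD-consuming enzymes, only Bst1 passed, over all tested genes and adjusted over the list alone (-1.35 ± 0.30; list adjusted p = 0.817). Members of the wider list of glucose uptake and glycolysis went both ways, with 4 of 25 rising and 2 falling (8 and 5 when adjusted over the list alone), Pgam1 at -0.88 ± 0.17 and Dlat at 0.42 ± 0.08 (list adjusted p = 0.532). Among 73 nuclear-encoded respiratory chain genes 2 rose, Ndufs1 (0.41 ± 0.11) and Uqcrc2 (0.38 ± 0.11), and 0 passed when adjusted over the list alone; the list's adjusted p = 0.0436 became adjusted p = 0.815 with an estimated correlation.

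Chaperones and genes of protein folding fell. Of 16 heat shock chaperones 10 fell, 0 rose and 6 did not pass (14 fell when adjusted over the list alone), with Hspa1a at -4.18 ± 1.13, Hsp90aa1 at -1.31 ± 0.21 and Hspa8 at -0.76 ± 0.12. Hspa1a varied widely between untreated floxed hearts (28.9 ± 28.1 CPM, SD). Hspa1b, a near-identical copy of Hspa1a, fell as well, and the separate values of the pair are uncertain. In the unfolded protein response 11 of 22 genes fell, 2 rose and 9 did not pass (14 fell and 2 rose when adjusted over the list alone); Pdia6 and Calr, residents of the endoplasmic reticulum, changed by -0.94 ± 0.13 and -0.82 ± 0.13, whereas Herpud1 rose by 0.79 ± 0.12. Both lists passed camera (adjusted p = 2.3e-11 and 1.1e-08) and both were at adjusted p = 0.343 with an estimated correlation. Of 21 tested immediate early genes, which respond rapidly to stimuli, Atf3 (-1.96 ± 0.55) and Ier3 (-0.56 ± 0.17) fell, over all tested genes and adjusted over the list alone, and 3 had positive values (median -0.36, adjusted p = 0.0142, and adjusted p = 0.690 with an estimated correlation). Members of the list of extracellular matrix and fibrosis fell in 5 of 30 cases and rose in 0 (7 fell when adjusted over the list alone), with Meox1 at -1.07 ± 0.29 and Col15a1 at -0.75 ± 0.20 (adjusted p = 1.2e-05, and adjusted p = 0.508 with an estimated correlation). Of 12 macrophage markers 7 fell and 0 rose (9 fell when adjusted over the list alone), Lyve1 at -1.11 ± 0.19 and Csf1r at -0.46 ± 0.13 (adjusted p = 1.8e-06, and adjusted p = 0.343 with an estimated correlation). The chemokine genes Ccl7 and Ccl2 changed by -1.86 ± 0.35 and -1.80 ± 0.40. Of 3 tested neutrophil markers S100a9 (-1.22 ± 0.31) and S100a8 (-1.58 ± 0.45) fell, as they did when adjusted over the list alone. All 7 MHC class II genes had negative values (median -0.45); 0 passed over all tested genes and 2 fell when adjusted over the list alone, with adjusted p = 0.00889 and adjusted p = 0.508 with an estimated correlation. None of 12 fibroblast markers passed, and their list median was -0.23.

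**Figure D1:**
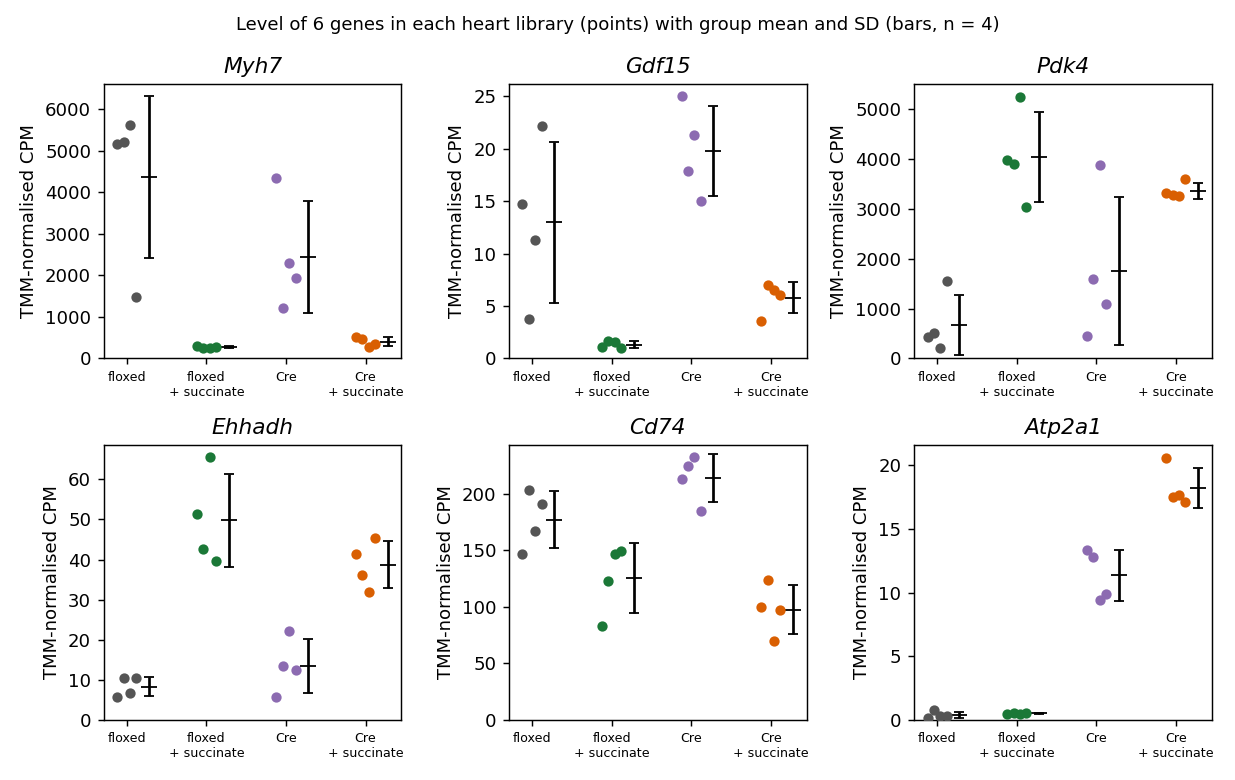
Each panel plots the TMM-normalised CPM of 1 gene on a linear axis from 0, with 1 point per library and the group mean and SD (n = 4) beside it, for floxed and Cre hearts with and without succinate. Myh7 was at 268 ± 29.2 CPM in floxed hearts with succinate against 4369.9 ± 1946 without, and Atp2a1 was at 11.4 ± 1.99 CPM in untreated Cre hearts against 0.365 ± 0.258 in untreated floxed hearts.

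The count of 1917 fell to 1150 and 1079 without replicate 1 or 3 of the untreated floxed hearts and to 1018 and 1071 without replicate 1 or 3 of the floxed hearts given succinate. On deposited FPKM with a mean of at least 1, 43.3% of the calls were higher, against 57.0% on the counts, and with an atrial marker score as a covariate 239 genes passed. That score was itself -0.115 ± 0.209 in untreated floxed hearts and -0.453 ± 0.102 in those given succinate (SD). As a covariate it can take up part of the succinate effect.

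In Cre hearts succinate moved several of the same genes in the same direction, and genes of MHC class II antigen presentation fell. Myh7 fell by 2.60 ± 0.41 (log2, SE, n = 4 per group), from 2449.9 ± 1347 to 405 ± 107 CPM (SD), and Ankrd1 by 0.89 ± 0.16. Ehhadh rose 2.90-fold, the muscle gene Klhl33 by 1.59 ± 0.25 and Pfkfb1, a regulator of glycolytic flux, by 1.45 ± 0.26 on the log2 scale. Cd74, the invariant chain of MHC class II, fell from 214 ± 21.0 to 97.6 ± 21.9 CPM. By the same test 134 genes passed, 88 higher and 46 lower, 29 of them by at least 2-fold.

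All 7 MHC class II genes fell over all tested genes and when adjusted over the list alone, including the class II transactivator Ciita (-1.62 ± 0.27), H2-Ab1 (-1.22 ± 0.20) and H2-DMb1 (-1.14 ± 0.23). This list passed camera at its preset correlation (adjusted p = 9.6e-23) and alone did so with the estimate (adjusted p = 0.0241 with an estimated correlation). Ccr2, a monocyte chemokine receptor, changed by -2.06 ± 0.44, the single macrophage marker of 12 that passed; all 12 had negative values and 3 fell when adjusted over the list alone, and the list had adjusted p = 3.1e-06, and adjusted p = 0.240 with an estimated correlation.

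Of 25 fatty acid oxidation genes 1 rose and 24 did not pass, although 25 had positive values and 9 rose when adjusted over the list alone. Sarcomere genes had a median of 0.16, with 16 of 17 values positive (adjusted p = 0.000834, and adjusted p = 0.296 with an estimated correlation). The fatty acid oxidation list's adjusted p = 4.6e-11 became adjusted p = 0.240 with an estimated correlation. No PPAR-alpha target passed over all tested genes (3 rose when adjusted over the list alone); Slc25a34 was at 0.53 ± 0.14 and Plin5 at 0.58 ± 0.16, with adjusted p = 5.1e-07 for the list and adjusted p = 0.230 with an estimated correlation. In branched-chain amino acid catabolism Bcat2 (0.49 ± 0.08), Ppm1k (0.63 ± 0.12) and Mccc2 (0.51 ± 0.11) rose, 0 of 19 fell and 13 rose when adjusted over the list alone; the list had adjusted p = 4.4e-14, and adjusted p = 0.142 with an estimated correlation. In the TCA cycle Dlst (0.40 ± 0.09) and Idh3a (0.39 ± 0.09) rose (5 of 20 when adjusted over the list alone), with adjusted p = 2.1e-09 and adjusted p = 0.230 with an estimated correlation. Oxct1 rose by 0.63 ± 0.09. No gene of NAD synthesis and transport passed, over all tested genes or adjusted over the list alone; Naprt was at 0.38 ± 0.12 and Nmrk2 at -2.10 ± 0.66 (list adjusted p = 0.837). Of 16 heat shock chaperones 0 passed over all tested genes and 13 fell when adjusted over the list alone, with adjusted p = 2.7e-13 and adjusted p = 0.142 with an estimated correlation. Gdf15 changed by -1.77 ± 0.37, and in the unfolded protein response Pdia6 fell (-0.64 ± 0.13) and Herpud1 rose (0.58 ± 0.12), while 20 of 22 genes did not pass (14 fell and 1 rose when adjusted over the list alone; adjusted p = 7.4e-09, and adjusted p = 0.230 with an estimated correlation). Of 15 cardiac stress genes 2 fell and 13 did not pass (3 fell when adjusted over the list alone), with adjusted p = 5.1e-07 and adjusted p = 0.142 with an estimated correlation.

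The count of 134 depended on single libraries. It was 28 without replicate 1 of the untreated Cre hearts, and 28, 62, 49 and 22 without replicates 1, 2, 3 and 4 of the Cre hearts given succinate; DESeq2 called 483.

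**Figure D2:**
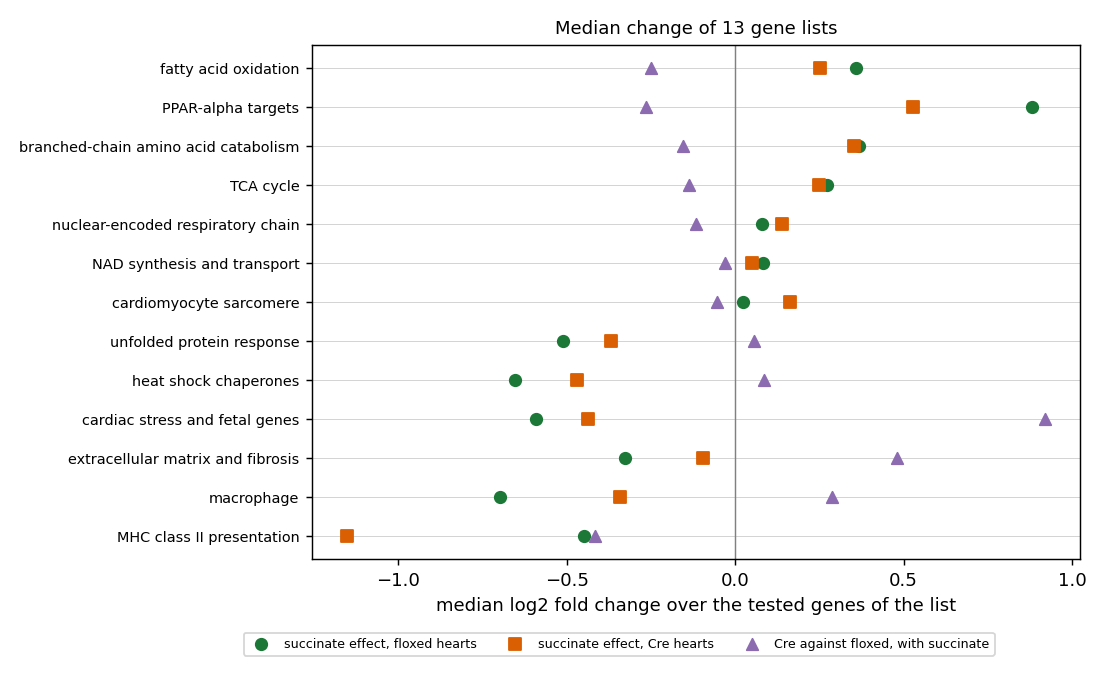
Each point is the median log2 fold change over the tested genes of a list: circles for succinate in floxed hearts, squares for succinate in Cre hearts and triangles for Cre against floxed hearts with succinate. The fatty acid oxidation median was 0.36 in floxed and 0.25 in Cre hearts given succinate, and the MHC class II median was -0.45 and -1.15.

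The succinate effects of the genotypes were then set against each other, from libraries that the 2 comparisons did not share. Of the genes that rose in floxed hearts, 81 also rose in Cre hearts, where 6.58 would be shared by independent lists. Of those that fell, 32 also fell, where 2.59 would be. The 2 comparisons shared an estimate of the spread per gene, so full independence is only a reference. No gene was called in opposite directions. Of the 1093 genes that rose in floxed hearts, 96.4% had a positive value in Cre hearts. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.572, and at r = 0.406 without replicate 1 of the untreated Cre hearts.

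**Figure D3:**
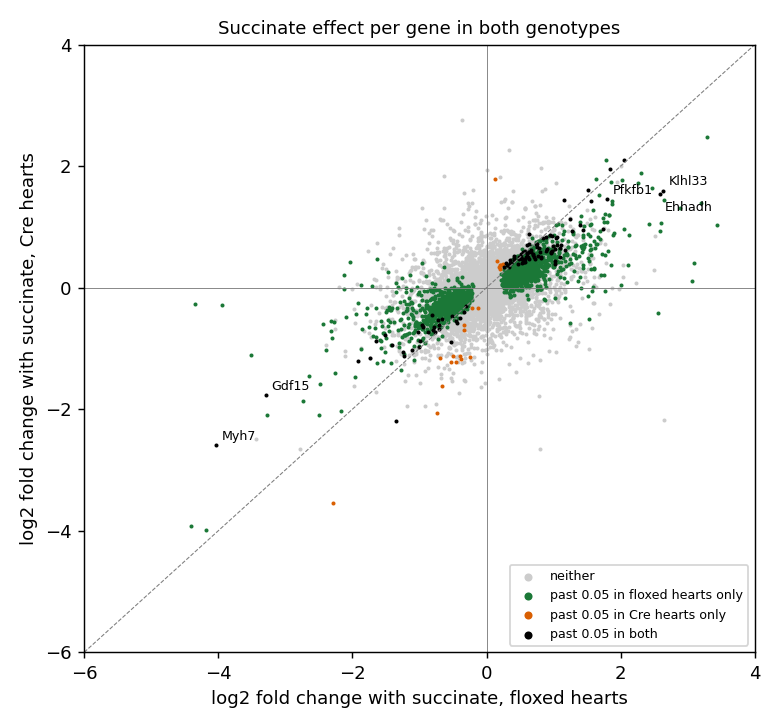
Each point is 1 of 14607 genes, with its log2 fold change with succinate in floxed hearts on the horizontal axis and in Cre hearts on the vertical axis; colours show where it passed an adjusted p of 0.05, the dashed line marks equal effects, and 1 gene lies outside the axes. Myh7 lies at -4.03 and -2.60, and Ehhadh at 2.58 and 1.54.

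The test of the difference itself, the genotype by succinate interaction, called 0 genes in edgeR, with 709 at an unadjusted p under 0.05 and a smallest adjusted p of 0.930. DESeq2 called 3, limma voom with sample weights 0, and limma on log2(FPKM + 1) 2. Nppb was at 1.60 ± 0.41 and Ankrd1 at 0.76 ± 0.23 (log2 difference of the succinate effects, Cre minus floxed), and Ucp3 at -1.58 ± 0.70, Ehhadh at -1.05 ± 0.43 and Bst1 at 1.28 ± 0.41, none past the threshold. Xrn2 (-0.63 ± 0.13) and Cited2 (-0.97 ± 0.23) were among the 10 genes of smallest p. At the preset correlation 15 of 41 lists passed, with MHC class II presentation lower (adjusted p = 1.8e-07) and cardiac stress genes higher (adjusted p = 2.0e-06) in the interaction; both were at adjusted p = 0.292 with an estimated correlation, and 0 lists passed that way. Without 2 libraries chosen after the data were seen, replicate 4 of the untreated floxed and replicate 1 of the untreated Cre hearts, 7 genes passed.

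The effect of genotype without succinate was carried by few genes, several of them typical of skeletal muscle. Atp2a1, the calcium pump of fast skeletal muscle, was 30.0-fold higher in Cre hearts (11.4 ± 1.99 against 0.365 ± 0.258 CPM, SD, n = 4 per group). The fast troponin I gene Tnni2 rose by 2.49 ± 0.35, Cyp2b10 by 3.59 ± 0.27 and the neuronal ubiquitin hydrolase gene Uchl1 by 0.90 ± 0.12 (log2, SE). Eif3j2 (-1.49 ± 0.26), Dcakd (-0.59 ± 0.11) and Tfpi (-0.53 ± 0.09) fell. Cyp2b10 and Eif3j2 have close paralogs, so reads assigned to them are uncertain. In edgeR 16 genes passed, 13 higher and 3 lower in Cre hearts.

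Of 5 tested skeletal muscle genes 2 rose, 3 did not pass and 5 had positive values (3 rose when adjusted over the list alone); this list passed camera (adjusted p = 1.9e-29) and did so with the estimate (adjusted p = 0.000172 with an estimated correlation). Of 15 cardiac stress genes 2 rose, Uchl1 and the slow troponin I gene Tnni1 (2.93 ± 0.47), and 6 rose when adjusted over the list alone, with adjusted p = 2.2e-06 and adjusted p = 0.274 with an estimated correlation. No fatty acid oxidation, TCA cycle, respiratory chain or NAD gene passed over all tested genes; adjusted over the list alone, Idh2 fell in the TCA cycle list and Nt5e rose in that of NAD synthesis. Idh2 was at -0.40 ± 0.11, Eci1 at -0.36 ± 0.13, Cox6a2 at -0.44 ± 0.15 and Nt5e at 0.70 ± 0.19. Respiratory chain genes had positive values in 1 of 73 cases, with adjusted p = 2.4e-08 and adjusted p = 0.527 with an estimated correlation. The mean log2 level of cytosolic ribosomal protein genes, relative to all libraries, was 0.00722 ± 0.0848 in untreated Cre and 0.201 ± 0.229 in untreated floxed hearts (SD). These spreads overlap. All 7 MHC class II genes had positive values (median 0.34) and 0 passed over all tested genes or adjusted over the list alone, with adjusted p = 0.00102 and adjusted p = 0.414 with an estimated correlation. The count of 16 was 7 and 4 without replicate 1 or 3 of the floxed hearts, 3 when only the 2 groups were fitted, and 86 in DESeq2.

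With succinate, Cre hearts differed from floxed hearts in skeletal muscle genes again and in cardiac stress genes. Atp2a1 was 36.2-fold higher (18.2 ± 1.59 against 0.502 ± 0.0537 CPM, SD, n = 4 per group), Tnni2 rose by 2.43 ± 0.34 and Casq1, the skeletal calsequestrin, by 1.99 ± 0.34 (log2, SE). Nppa was 8.73-fold higher (693 ± 246 against 79.4 ± 12.2 CPM), and Gdf15 rose by 2.14 ± 0.43. Adra1a, an alpha-1 adrenergic receptor, changed by -0.94 ± 0.18. In edgeR 101 genes passed, 80 higher and 21 lower in Cre hearts.

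Of 15 cardiac stress genes 6 rose, 0 fell and 9 did not pass (10 rose when adjusted over the list alone), including Ankrd1 (1.11 ± 0.16), Mybpc2 (0.93 ± 0.14) and Uchl1 (0.92 ± 0.12). The list passed at adjusted p = 4.5e-23, and at adjusted p = 0.00426 with an estimated correlation. Its member Mybpc2 is also among the chromosome 7 calls described below. So are Atf5 of the integrated stress response list, Atp2a1, Tnni2 and Tnnt3 of the skeletal muscle list, and Dkk3 of the atrial list. These list results are therefore not separate from the chromosome 7 pattern. Of 14 amino acid genes of the integrated stress response 4 rose, the mitochondrial folate enzyme Mthfd2 at 1.61 ± 0.23, Gdf15, the serine synthesis gene Psat1 at 0.69 ± 0.15 and Atf5 at 0.62 ± 0.13, and 6 rose when adjusted over the list alone (adjusted p = 1.05e-06, and adjusted p = 0.00913 with an estimated correlation). Skeletal muscle genes rose in 3 of 5 cases (4 when adjusted over the list alone), with Tnnt3 at 2.68 ± 0.44 (adjusted p = 3.0e-36, and adjusted p = 2.8e-05 with an estimated correlation). Of 7 tested atrial markers Nppa and Dkk3 (1.70 ± 0.38) rose, as they did when adjusted over the list alone, with adjusted p = 0.000574 and adjusted p = 0.0226 with an estimated correlation; Nppa belongs to the cardiac stress list as well. No fatty acid oxidation gene passed, and 0 of 25 had a positive value; Slc27a1 was at -0.47 ± 0.15 and Decr1 at -0.37 ± 0.12, with adjusted p = 8.2e-09 and adjusted p = 0.377 with an estimated correlation. No matrix gene passed over all tested genes and 9 of 30 rose when adjusted over the list alone; Col8a1 was at 0.85 ± 0.23, with adjusted p = 1.8e-16 and adjusted p = 0.148 with an estimated correlation. Fibroblast markers were positive in 12 of 12 cases beside it, with 8 rising when adjusted over the list alone and a median of 0.45 (adjusted p = 1.4e-08, and adjusted p = 0.129 with an estimated correlation). In the 2 NAD lists 0 genes passed over all tested genes, with Nampt at -0.28 ± 0.11 and Parp2 at -0.30 ± 0.08; adjusted over the list alone, 0 synthesis genes passed and 1 NAD-consuming enzyme rose and 1 fell.

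Of the 101 calls, 11 of the 80 higher genes and 1 of the 21 lower were called in the same direction without succinate, where 0.0712 and 0.00431 would be shared by independent lists. The 2 comparisons shared an estimate of the spread per gene, so their lists were not fully independent. The count of 101 was 46, 66 and 51 without replicates 1, 2 and 3 of the floxed hearts given succinate and 67, 44 and 56 without replicates 2, 3 and 4 of the Cre hearts given succinate. With an atrial marker score, which contains Nppa and Dkk3, as a covariate it was 3. That score was itself -0.453 ± 0.102 in floxed and 0.321 ± 0.163 in Cre hearts given succinate (SD). As a covariate it therefore takes up part of the genotype difference.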

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

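The scan for libraries apart from their group was widened to all named genes after a first pass over fewer genes had been seen, whereas the tests of list differences between the genotypes were planned. In 752 groups of 4 libraries, 4 for each of 185 named genes and 4 each for total counts, the mitochondrial share of counts and Sucnr1, 46 held a library whose gap to its nearest neighbour took up most of the group's range. Chance alone flags about 1 in 20 groups, here 37.6, so the number itself is near what chance gives. Values below are CPM of the library that stood apart.

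Among untreated floxed hearts, replicate 4 was apart for Myh7 (1468 against 5165 to 5635 in the others), Dlat (234), Opa1 (115), Lipe (86.9), Abcc9 (204), Slc2a4 (225), Hk2 (149) and Cox6a2 (1773). Replicate 2 was apart for Idh3a (467), Kcnj2 (18.1), Ddit3 (19.6), Smco1 (9.17) and Mybpc2 (24.6). Replicate 3 was apart for Bst1 (1.74) and Lyve1 (42.5), and replicate 1 for H1f2 (40.6). With succinate, replicate 1 of the floxed hearts was apart for Nadk2 (84.2), Cpt2 (294), Atf5 (30.0), Prkcz (0.817) and Acsl6 (20.4), and replicate 4 for Arrdc2 (55.3 against 24.7 to 27.5), Ier3 (27.4) and Rasd2 (5.89). Tgfb3 was apart in replicate 2 (18.5) and Parp2 in replicate 3 (13.9).

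Among untreated Cre hearts, replicate 1 was apart for Sdf2l1 (12.7 against 3.23 to 3.83), Pdia6 (122), Calr (379), Gpx3 (616), Rasd2 (1.39) and Atp5b (3599.5). The first 3 of these genes belong to protein folding in the endoplasmic reticulum. Replicate 3 was apart for Chrna2 (8.70) and Sirt5 (27.3), replicate 2 for Pdgfrb (89.2) and replicate 4 for Stum (8.07). With succinate, replicate 3 of the Cre hearts was apart for Dkk3 (8.89 against 4.05 to 4.17), Col8a1 (59.3 against 28.5 to 30.1), Hspb8 (405), Idh2 (1156) and Acsl6 (6.99). Tnni2 (5.98) and Nlrc3 (1.56) were apart in replicate 2, Atp2a1 (20.6) in replicate 1 and Pdk4 (3603) in replicate 4.

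The succinate effect differed between the genotypes for 15 of 41 lists by camera at its preset correlation, and for 0 with an estimated correlation. It was lower in Cre hearts for MHC class II presentation (adjusted p = 1.8e-07), PPAR-alpha targets (0.000274), fatty acid oxidation (0.00535) and erythroid markers (0.0116). It was higher for cardiac stress genes (2.0e-06), matrix genes (6.0e-05), immediate early genes (0.000111), smooth muscle and pericyte markers (0.00495) and inflammatory cytokines (0.0137). The same direction held for fibroblast (0.0145) and endothelial markers (0.0170), ribosomal proteins (0.0247), the unfolded protein response and the integrated stress response (both 0.0365) and heat shock chaperones (0.0497). Without replicate 1 of the floxed hearts given succinate, or without replicate 3 of the untreated Cre hearts, 8 lists passed.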

How the results depend on the processing

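The fit without replicate 4 of the untreated floxed and replicate 1 of the untreated Cre hearts was chosen after the data were seen. For the following counts the cause of each shift was not tested. For succinate in floxed hearts 1917 genes became 239 with the atrial score as a covariate, 3158 with the white adipocyte score (2 tested genes), 2925 with voom weights, 954 on log2(FPKM + 1) and 1122 on log2(FPKM + 0.1). For succinate in Cre hearts 134 became 213 and 525 with those scores, 46 with the 2 groups alone, 483 in DESeq2, 44 and 38 on FPKM, and 40 without the 2 libraries. For genotype without succinate 16 became 2 and 175 with the scores, 3 with the 2 groups alone, 86 in DESeq2, 7 on FPKM with a mean of at least 1, and 81 without the 2 libraries. For genotype with succinate 101 became 3 and 206 with the scores, 307 in DESeq2, 190 with voom weights, 41, 52 and 51 on FPKM with pseudocounts 1 and 0.1 and a mean of at least 1, and 158 without the 2 libraries. The interaction count of 0 became 3 in DESeq2, 2 and 1 on FPKM, and 7 without the 2 libraries. With an estimated correlation the lists past the threshold fell to 0, 1, 1, 4 and 0.

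Leaving out each library gave 1018 to 1989, 22 to 142, 4 to 23, 44 to 92 and 0 genes for the 5 comparisons, and 13 to 17, 18 to 21, 17 to 22, 17 to 22 and 8 to 19 lists. The correlation across genes ranged from 0.406 to 0.589 and the Sucnr1 difference from 0.109 to 0.195 CPM. Signs reversed with the atrial score in the genotype comparison with succinate for Dkk3 (-0.24), Slc25a34 (0.27), Cox6a2 (0.0844), Atp5b (0.0942), Thbs4 (-1.004) and Col8a1 (-0.0505), and in the interaction for Thbs1 (-0.23); Dkk3 is part of that score, and the cause was not tested for the rest. Ndufa11 reversed in the interaction without the 2 libraries (-0.0230), and the fatty acid oxidation list in the genotype comparison without succinate when replicate 1 of the untreated Cre hearts was left out (adjusted p = 0.802; 7.3e-08 to 0.802 over the libraries left out).

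Of the values of single named genes under the other settings 2905 kept direction and side of the threshold, 396 no longer passed and 39 newly passed. With a library left out these were 1773, 398 and 5. The kept values include those that did not pass in the main fit and so could not be lost. Among the named calls alone, 57 were kept, 110 lost and 1 reversed with the atrial score. Without replicate 2 of the untreated floxed hearts 100 were kept and 5 lost. Without replicate 4 of the Cre hearts given succinate 24 were kept and 39 lost.

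Replicate numbers did not pair the samples: 3 of 24 same-number pairs correlated above 0.1, and 5 of 16 libraries correlated best with their own number. With a replicate block 1903, 136, 11, 92 and 0 genes passed, and the Sucnr1 difference of 0.168 CPM passed (exact p = 0.0309). The planned sex covariate was not run, because every library had at most 5 counts of Xist and at least 1034 of Ddx3y. Depth limits Sucnr1, where 3 counts were 0.0865 to 0.108 CPM.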

Other observations

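The tests of Gene Ontology terms, the chromosome 7 excess, the linked segment, skeletal muscle, cell composition, sampling time and the splits of samples were chosen after the results were seen, and the comparison of single skeletal muscle transcripts was added after both sums of them were known; those of an extra chromosome, of the spread and of the size of the succinate effect were prompted by patterns already seen, with bounds written before their own values were. Outside the gene lists, the genes that fell with succinate in floxed hearts were rich in the cytoskeleton: 57 of 319 tested genes of actin binding fell where 18.6 were expected (Fisher's exact test, adjusted p = 7.3e-11), 21 of 86 of stress fibers (adjusted p = 8.3e-06) and 25 of 159 of focal adhesions (adjusted p = 0.00102). Peroxisome genes rose in 25 of 122 cases (9.29 expected, adjusted p = 0.00372). Of 12 genes of 2-oxoglutarate metabolism 7 rose in floxed hearts (adjusted p = 0.00378) and 4 in Cre hearts (adjusted p = 0.00251). Genes of muscle contraction control were higher in Cre than floxed hearts with succinate in 4 of 16 cases (adjusted p = 0.00499).

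In the circadian clock list, succinate in floxed hearts raised Per3 (0.86 ± 0.19) and Nr1d2 (0.53 ± 0.12) and lowered Cry1 (-0.81 ± 0.15) and Bhlhe40 (-0.68 ± 0.18); of its 18 tested genes 3 rose, 2 fell and 13 did not pass (5 rose and 2 fell when adjusted over the list alone), and the list did not pass (adjusted p = 0.389). Ryr2 (0.72 ± 0.20), Atp2a2 (0.46 ± 0.13) and Kcnj2 (1.31 ± 0.36), genes of calcium release, calcium uptake and potassium current, rose in the same hearts; of the 19 tested genes of calcium handling and ion channels 6 rose, 1 fell and 12 did not pass (9 rose and 2 fell when adjusted over the list alone), and the list did not pass (adjusted p = 0.0876, and adjusted p = 0.692 with an estimated correlation). All 20 cell cycle genes had positive values in Cre against floxed hearts with succinate (median 1.19, adjusted p = 8.0e-08, and adjusted p = 0.307 with an estimated correlation). Of them 0 passed over all tested genes and 4 rose when adjusted over the list alone. Without succinate the list's mean log2 level, relative to all libraries, was higher in Cre hearts as well (0.381 ± 0.447 against -0.433 ± 0.714, SD).

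Genes of chromosome 7, placed by the GRCm38.p6 table, were overrepresented among genotype calls: 9 of 16 without succinate and 22 of 101 with it, against 7.65% of tested genes (Fisher's exact test, adjusted p = 1.2e-05 and 0.000120). They include Atp2a1, Tnni2, Cyp2b10 and Ryr1, the last chosen after its values were seen, and 7 were called in both comparisons; with succinate chromosome 19 was overrepresented too (10 of 101 calls against 3.50% of tested genes, adjusted p = 0.0278). An extra chromosome is argued against by a median of -0.0445 over 1107 chromosome 7 genes, and a single linked segment holding most calls by the fullest window of 111 genes, with 22.7% of the 22 calls with succinate (permutation p = 0.904), 33.3% of the 9 without (permutation p = 0.816) and 42.9% of the 7 called in both (permutation p = 0.527), the last 2 from few genes. Carried-over skeletal muscle stays open: 6 fast transcripts together rose by 0.116 of the rise of Atp2a1 and none of 8, Tnni2 and Myl1 included, by more than 0.206 (0.304 at most leaving out each library), but the 8 summed to 0.519 (0.456 to 0.647), on both sides of the bound of 0.5 set for the 6, and reading these ratios assumes a muscle profile with such transcripts near the level of Atp2a1, which was not measured here. A wider block of strain-derived sequence could remain, and no Cre-only group exists here to part the transgene from the deletion.

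Succinate called 1917 genes in floxed and 134 in Cre hearts. A wider spread in Cre hearts for the typical gene is argued against by a ratio of median SDs of 0.961 (0.878 to 1.10 leaving out each library). That ratio does not cover single gene lists, which went both ways. The SD of a list's mean log2 level between untreated libraries was 0.266 in Cre and 0.119 in floxed hearts for fatty acid oxidation. For the TCA cycle it was 0.158 and 0.0377, and for MHC class II genes with succinate it was 0.311 and 0.455. A wider spread in some of the lists that succinate moved thus stays open. A smaller effect in Cre hearts cannot be told apart from an equal one: the noise-corrected slope was 0.638 with a jackknife SE of 0.257, and 0.465 without replicate 1 of the untreated Cre hearts. The slope lay within 2 SE of 1, which was set as evidence against a smaller effect, but the same interval holds slopes far below 1 and excludes neither. A difference in the succinate response by genotype may exist as a hypothesis, and the gene-level interaction test did not show it.

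With succinate the median log2 change of 25 fatty acid oxidation genes was 0.36 in floxed hearts, where 13 rose, and 0.25 in Cre hearts, where 1 rose (adjusted p = 0.343 and 0.240 with an estimated correlation). A lower share of non-myocytes as the whole cause is argued against by sarcomere medians of 0.0237 (quartiles -0.03 to 0.23) and 0.162 (0.09 to 0.22), with a thin margin in Cre hearts, where the sarcomere list passed camera (adjusted p = 0.000834, and adjusted p = 0.296 with an estimated correlation) and a part could still come from it. A different sampling time was read from 9 clock genes, a set picked after their values were seen. It cannot be told apart in floxed hearts, where their median was 0.535 (quartiles 0.45 to 0.76). In Cre hearts a median of 0.105 (quartiles 0.02 to 0.28) argues against a shift as large as in floxed hearts. A smaller shift in the same direction stays open there. Feeding before sampling was not tested.

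For succinate in floxed hearts 1 of the 35 splits of the 8 samples gave as many genes, the real one with 1917, and the highest other gave 1. The same held in Cre hearts (1 of 35, real 134, highest other 1) and for genotype with succinate (1 of 35, real 101, highest other 1). A share of 1 in 35 is the smallest these splits can give, and they were chosen after the results were seen. They argue against chance in these comparisons without excluding it, and they cannot tell the labels from another structure of the samples that follows them. For genotype without succinate 4 of 35 splits gave 16 or more and the highest other gave 78, several times the real count, so chance was not excluded for the number of calls. The 3 other splits all placed replicate 1 of the untreated Cre hearts with replicates 1 and 3 of the untreated floxed hearts, which points to a structure of the samples. Of the 13 higher genes, however, 11 were called again in the separate libraries given succinate, where 0.0712 would be shared by independent lists. The skeletal muscle list passed camera (adjusted p = 0.000172 with an estimated correlation). That list result comes from the same libraries and includes Atp2a1 and Tnni2 of these calls, so it adds no separate evidence. For the interaction the real count of 0 is reached by all 100 drawn splits whatever the data, so they say nothing about chance. The highest gave 1355, a regrouping that kept the succinate labels of the floxed hearts and changed those of the Cre hearts.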
